A study of Rattus norvegicus with 36 samples.

How the data were processed

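Liver RNA of male rats was measured on 36 Affymetrix 3' expression arrays, 6 for vehicle and 6 for each of 5 daily doses of decaBDE (959, 95.9, 9.59, 0.959 and 0.1 mg/kg by gavage in 5 ml/kg corn oil for 5 days). Per the labels, RNA had to meet limits of concentration, purity and integrity before use. The deposited values are log2 RMA signals, background-corrected, quantile-normalized and summarised per probe set by the authors with the affy package, whose version is not given. They ran from 2.02 to 15.0, with no value missing and nearly equal quartiles in every array. All 36 sample columns were used. Groups and replicate numbers were taken from the sample titles.

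Of 31099 probe sets, 57 array controls were left out and 31042 were tested. The annotation gave 1 gene symbol to 20826 probe sets, several to 436 and none to 9780. For 20758 of the first, the gene ID was found in the current RefSeq table, and 0 symbols differed. Where several probe sets carried 1 gene, lists and named genes used the one with the highest mean over all arrays, which gave 14217 genes. No gene is named from a probe set with several symbols, so Cyp2b1, Cyp2b2, Ugt1a1 and Ugt1a6 are not given by name, and 1 other gene chosen in advance is not reported here. No genome positions are given, since the array files name no genome build.

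Each probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 mean per group, 30 residual and 5.12 prior degrees of freedom). Two-sided contrasts compared each dose with vehicle and 959 with 95.9 mg/kg. A moderated F-test asked about any dose, and a contrast tested a straight line in dose rank (0 for vehicle to 5). P-values were adjusted by Benjamini-Hochberg over all probe sets within each comparison, with a threshold of 0.05, which follows the false discovery rate of 5% in the series' design text. That text names the maanova package, which was not at hand, so limma took its place, and a fit without variance moderation stood in as the nearest alternative. Errors are limma's standard errors or SDs over arrays, as marked, and intervals are at 95%. An array count beside a gene says how many arrays of 6 lay above or below every vehicle array.

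28 gene lists were written from general knowledge before the data were examined. They were targets of CAR and PXR, AhR, PPARA and NRF2. Others covered thyroid hormone response, cholesterol synthesis, fatty acid and triglyceride synthesis, bile acids, gluconeogenesis and fasting, cell cycle, p53 and DNA damage, unfolded protein and integrated stress, heat shock, acute phase, interferon, circadian clock, and growth hormone and male-specific genes. The rest were markers of hepatocytes, pericentral and periportal hepatocytes, Kupffer cells and macrophages, stellate cells and fibroblasts, endothelium, cholangiocytes, lymphocytes, neutrophils, erythroid cells and exocrine pancreas. Each list at each dose was tested with camera at a preset correlation of 0.01 between genes (140 tests, adjusted together), and again with an estimated correlation and with fry, which tests whether a list's genes move on balance in 1 direction. Members were counted at the threshold over all probe sets and adjusted over the list alone. Lists can share members, and a shared gene counts in each, so lists are not independent of each other. Ephx1 is in the CAR and PXR and the NRF2 lists, and Nqo1 in the AhR and NRF2 lists. Cyp1a2 is in the AhR and pericentral lists, and Sds and Pck1 in the gluconeogenesis and periportal lists. The mean of a list's centred members per array is its score.

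The rule for named genes was also set before the data were examined. It took up to 10 genes with the largest rise and 10 with the largest fall past the threshold at 959 mg/kg, filled to 5 by the smallest unadjusted p, and up to 5 per direction in the other comparisons, or 2 by the smallest unadjusted p where none passed. It added up to 4 members of each list with the smallest p at 959 mg/kg and 16 genes followed whatever their values. Shared probe sets of the Cyp2b and Ugt1a genes are given as such, with no gene name. Where a gene's other probe sets differ in their call, this is said.

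On simulated arrays with the same layout, 22% of 50 probe sets with a true log2 change of 0.25 were called, 90% at 0.5 and 100% at 1, with 6 false calls among 31042 probe sets. A simulated shift of 0.3 in 1 list was called, and 0 of 139 other list tests were. The simulated genes varied independently of each other, so these counts do not measure false list calls among genes that vary together.

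Alternatives were another quantile normalization, values minus each array's median, only probe sets at or above the median level, only the brightest probe set per gene, no variance moderation, an intensity trend with robust estimation, array weights, the replicate number as a block, only the arrays of the compared groups, each array left out, other dose scales for the trend, and other list tests. Leaving out the array that stood apart from every comparison, the interferon score as a covariate, and the added dose steps were chosen after the data were seen. Other groupings of the arrays were drawn at random (100 per comparison, the real one included, with a fixed seed). Correlations between scores used deviations from group means and 100000 permutations.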

Results

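Gene expression was measured on Affymetrix arrays in the liver of male Harlan Sprague Dawley rats given decabromodiphenyl ether (decaBDE), a brominated flame retardant, by gavage in corn oil. The rats were 7 weeks old at the start and received corn oil alone or 1 of 5 doses on 5 consecutive days, the lowest 0.1 mg/kg and the highest 959 mg/kg, with 0.959, 9.59 and 95.9 mg/kg between them. The left liver lobe was taken 1 day after the last dose. There were 6 groups of 6 arrays, 36 arrays in all, and 31042 probe sets were tested on the log2 RMA scale. Array medians ran from 5.13 to 5.21, and Pearson's r between arrays, across probe sets that are not independent replicates, ran from 0.988 to 0.996. The labels do not state outright that each array came from its own rat, so every p-value measures the spread between arrays, and 6 arrays per group limit the precision. Replicate 6 of the 0.1 mg/kg group stood apart from the other arrays, with the lowest estimated array weight (0.517) and a score of -28.3 on the first principal component, which held 9.94% of the variance. Values are against vehicle unless another group is named. Adjusted p-values of genes and lists are from limma, and those of relations between scores are from permutations.

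The comparison of 0.1 mg/kg with vehicle asked which liver transcripts differed at the lowest dose, and no probe set passed. A probe set assigned to 2 genes of the Cyp2b subfamily of drug-metabolizing enzymes had a log2 fold change of 0.49 (SE 0.177, adjusted p = 1), and 2 of 6 arrays lay above every vehicle array. The probe sets with the smallest unadjusted p had log2 fold changes of 0.30 (LOC100910237), 0.30 (Mcts2), -0.34 (B3gnt5, a glycosyltransferase gene) and -0.38 (Prrg3), each with adjusted p = 1. limma left 1175 probe sets (3.79%) with an unadjusted p under 0.05, and the same model without variance moderation also called 0. By camera with a preset correlation between genes, 3 lists fell. They were the interferon response (24 genes, median log2 fold change -0.293, adjusted p = 3.75e-07), the Kupffer cell and macrophage markers (12 genes, -0.397, adjusted p = 1e-07) and the lymphocyte markers (15 genes, -0.108, adjusted p = 0.0348). With an estimated correlation the adjusted p-values were 0.398, 0.177 and 0.526. Of their members 0 passed on their own, over all probe sets or adjusted over the list alone. The 3' to 5' difference of actin, a sign of RNA quality, had a mean of 1.24 (SD 0.145, n = 6) at 0.1 mg/kg and 1.16 (SD 0.0483, n = 6) in vehicle. Within groups it went with lower interferon (Pearson's r -0.468, adjusted p = 0.02 over 8 relations) and macrophage scores (r -0.515, adjusted p = 0.011). The interferon score also varied among vehicle arrays, with an SD of 0.463 (n = 6) against 0.429 over all 36 arrays. The lymphocyte call was lost without vehicle replicate 4 or 5 or without 0.1 mg/kg replicate 1 or 5 (adjusted p up to 0.512).

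At 0.959 mg/kg, targets of the receptors CAR and PXR, which induce drug-metabolizing enzymes, rose as a list. Their median log2 fold change was 0.193 (adjusted p = 7.92e-14 and, with an estimated correlation, 0.001), and of the 24 measured targets 3 rose over all probe sets and 7 when adjusted over the list alone. The Cyp2b-subfamily probe set rose 4.21-fold (log2 2.07, SE 0.177, adjusted p = 3.32e-09), from a mean of 10.96 (SD 0.64, n = 6) to 13.04 (SD 0.15, n = 6). Cyp3a23-3a1, a cytochrome P450 induced through the receptor PXR, rose by 0.41 (SE 0.0651, adjusted p = 0.00216). Cyp2c6v1, another P450 gene, rose by 0.29 (SE 0.0462, adjusted p = 0.00216). Ugt2b1, a glucuronosyltransferase gene, rose by 0.60 (SE 0.118, adjusted p = 0.041). Outside the list, Mmgt1, a membrane magnesium transporter gene, rose by 0.54 (adjusted p = 0.000251), and Stbd1, whose product binds glycogen, by 0.50 (adjusted p = 0.0228). All 6 arrays lay above every vehicle array for each of these except Ugt2b1 (5 of 6).

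In all, 9 probe sets passed at 0.959 mg/kg, 9 up and 0 down, which covered 5 genes named by 1 symbol. The smallest unadjusted p among decreases belonged to Plcg2 (-0.32, adjusted p = 0.0979) and Il2rg (-0.42, adjusted p = 0.381), both signalling genes of blood cells. A fit of these 2 groups alone called 1 probe set, and the count was 5, 4 and 5 without vehicle replicate 2, vehicle replicate 5 and 0.959 mg/kg replicate 2. The Ugt2b1 call was lost without any 1 of 9 arrays (adjusted p up to 0.198: vehicle replicates 1, 2, 3 and 5 and 0.959 mg/kg replicates 1, 2, 4, 5 and 6). The Stbd1 call was lost without any 1 of 7 (up to 0.145: vehicle replicates 2, 3 and 5 and 0.959 mg/kg replicates 1, 2, 4 and 5).

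None of the other lists called at 0.959 mg/kg passed with an estimated correlation, and of these only the periportal markers held with fry. Cholesterol synthesis genes rose (20 of 20 positive, median 0.208, adjusted p = 9.7e-12) with an adjusted p = 0.129 with an estimated correlation. Of its members 0 passed, and Dhcr7, the last enzyme of the pathway, had a log2 fold change of 0.27 and Pmvk 0.25. Cell cycle genes rose (30 of 35 positive, median 0.15, estimated-correlation adjusted p = 0.417). So did heat shock genes (12 of 12 positive, 0.095, estimated 0.194), fatty acid and triglyceride synthesis genes (0.089, estimated 0.536) and targets of NRF2, the regulator of antioxidant genes (0.139, estimated 0.241). Lists that fell were the Kupffer cell and macrophage markers (median -0.453, estimated-correlation adjusted p = 0.222), the interferon response (-0.258, estimated 0.626) and lymphocyte markers (-0.16, estimated 0.177). As at 0.1 mg/kg, the 3' to 5' difference of actin, which within groups went with lower interferon and macrophage scores, had a higher mean (1.23, SD 0.109, n = 6) than in vehicle (1.16). Other lists that fell were endothelial markers (-0.098, estimated 0.124), periportal hepatocyte markers (-0.145, estimated 0.0561), bile acid genes (-0.079, estimated 0.371) and gluconeogenesis genes (-0.062, estimated 0.16). Adjusted over the list alone, 3 macrophage markers fell, among them Adgre1 (-0.66) and Csf1r (-0.43). So did 4 endothelial markers, among them Kdr (-0.21) and Tek (-0.30), and 1 periportal marker, the histidine-degrading enzyme Hal (-0.30). None of these members passed over all probe sets. Leaving out a single array ended 4 of these list calls. The fatty acid call was lost without any 1 of 7 arrays (vehicle replicates 1, 2 and 3 and 0.959 mg/kg replicates 1, 2, 4 and 6, adjusted p up to 0.211). The bile acid call was lost without vehicle replicate 4 or 0.959 mg/kg replicate 2 (up to 0.143), and the gluconeogenesis call without vehicle replicate 2 or 0.959 mg/kg replicate 2 (up to 0.0995). The interferon call was lost without 0.959 mg/kg replicate 4 (0.0743).

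**Figure D1:**
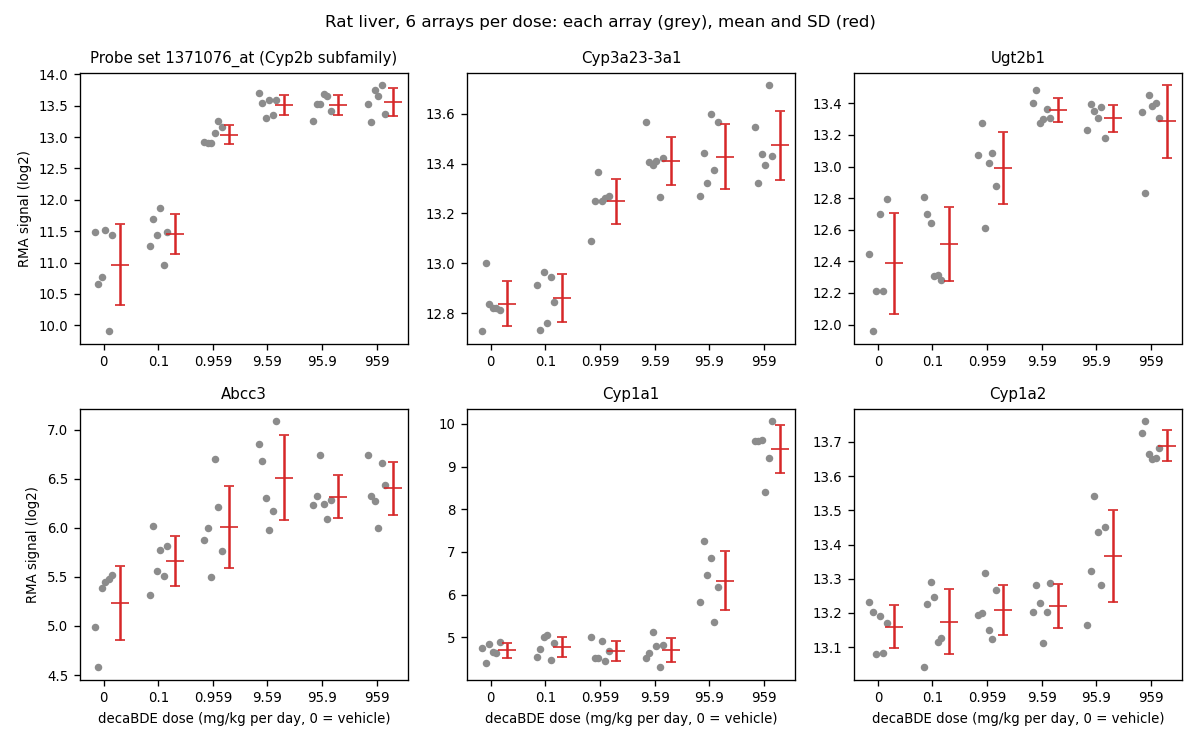
Log2 RMA signal (vertical axis) of 5 genes and 1 Cyp2b-subfamily probe set in each array by decaBDE dose in mg/kg (horizontal axis, evenly spaced groups), with grey points for the 6 arrays of each group and red marks for mean and SD. The Cyp2b-subfamily signal rises from 10.96 in vehicle to 13.04 at 0.959 mg/kg and 13.56 at 959 mg/kg, and Cyp1a1 from 4.69 in vehicle to 6.33 at 95.9 and 9.41 at 959 mg/kg.

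At 9.59 mg/kg the CAR and PXR targets had a median log2 fold change of 0.287 (adjusted p = 2.9e-19 and 1e-04 with an estimated correlation); 8 of 24 rose over all probe sets and 16 adjusted over the list alone. The Cyp2b-subfamily probe set rose 5.86-fold (log2 2.55, SE 0.177, adjusted p = 7.55e-12). Abcc3, a transporter that exports conjugates from hepatocytes, rose 2.43-fold (log2 1.28, SE 0.183, adjusted p = 0.000126). Ugt2b1 rose by 0.97 (SE 0.118, adjusted p = 9.94e-06) and Ces2c, a carboxylesterase gene, by 0.95 (SE 0.119, adjusted p = 1.52e-05). Outside the list, Mmgt1 rose by 0.59 (SE 0.0737, adjusted p = 1.46e-05) and Cndp2, a peptidase gene, by 0.58 (SE 0.0741, adjusted p = 1.91e-05). Each of these lay above all vehicle arrays in 6 of 6 arrays. Cyp3a23-3a1 rose by 0.58 (adjusted p = 2.85e-06), Cyp2c6v1 by 0.33 (adjusted p = 7.5e-05). Ephx1, the microsomal epoxide hydrolase, rose by 0.40 (adjusted p = 0.00466) and Por, the electron donor of P450 enzymes, by 0.49 (adjusted p = 0.0334). Adamts8, a metalloproteinase gene, fell by 0.34 (SE 0.0661, adjusted p = 0.0147) at a level of 3.21 in vehicle, below the median of all probe sets (5.16).

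In all, 36 probe sets passed at 9.59 mg/kg, 33 up and 3 down. Periportal hepatocyte markers fell together (11 of 11 negative, median -0.154, adjusted p = 6.24e-07 and 0.00739 with an estimated correlation). Over all probe sets 0 members passed and 4 adjusted over the list alone, among them Gls2 (-0.23), a glutaminase, and Hal (-0.26). Of the bile acid genes (median -0.016, mean -0.136, estimated-correlation adjusted p = 0.271), 3 fell when adjusted over the list alone, among them the canalicular sterol and phospholipid transporters Abcg8 (-0.99) and Abcb4 (-0.27). NRF2 targets rose (median 0.161, estimated-correlation adjusted p = 0.261) with the preset correlation. Gluconeogenesis genes (-0.062, estimated 0.124), the interferon response (-0.152, estimated 0.782) and hepatocyte markers (-0.023, estimated 0.177) fell. So did macrophage (-0.289, estimated 0.484), endothelial (-0.087, estimated 0.298) and lymphocyte markers (-0.145, estimated 0.168), all with the preset correlation. The 3' to 5' difference of actin had a mean of 1.2 (SD 0.0887, n = 6) at this dose against 1.16 in vehicle, and that of GAPDH -0.0308 (SD 0.0562, n = 6) against -0.0805 (SD 0.0397, n = 6). Leaving out a single array ended 5 of these list calls. The interferon call was lost without any 1 of 5 arrays (vehicle replicates 1 and 5 and 9.59 mg/kg replicates 1, 3 and 4, adjusted p up to 0.318). The hepatocyte call was lost without any 1 of 6 (vehicle replicates 2, 3 and 6 and 9.59 mg/kg replicates 1, 3 and 4, up to 0.121). The endothelial call was lost without any 1 of 4 (vehicle replicates 3 and 6 and 9.59 mg/kg replicates 2 and 4, up to 0.176). The bile acid call was lost without 9.59 mg/kg replicate 4 (0.161) and the gluconeogenesis call without vehicle replicate 2 (0.0556).

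A fit of these 2 groups alone called 19 probe sets, and the count was 20 without 9.59 mg/kg replicate 1. The Por call was lost without any 1 of 7 arrays (adjusted p up to 0.131: vehicle replicates 1, 2, 3 and 5 and 9.59 mg/kg replicates 1, 2 and 3) and on its other probe set (0.37, adjusted p = 0.242). The Adamts8 call was lost without any 1 of 4 (up to 0.0705: vehicle replicates 2, 3 and 6 and 9.59 mg/kg replicate 6).

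At 95.9 mg/kg a target of the aryl hydrocarbon receptor (AhR) was called beside these genes. Cyp1a1, the P450 most strongly induced through that receptor, rose 3.1-fold (log2 1.63, SE 0.222, adjusted p = 4.38e-05), from a mean of 4.69 (SD 0.17, n = 6) to 6.33 (SD 0.69, n = 6), with 6 of 6 arrays above every vehicle array. The Cyp2b-subfamily probe set rose 5.86-fold (adjusted p = 7.67e-12) and Abcc3 by 1.09 (SE 0.183, adjusted p = 0.00184). Ces2c rose by 0.96 (SE 0.119, adjusted p = 1.01e-05), Ugt2b1 by 0.92 (SE 0.118, adjusted p = 1.53e-05) and Cyp3a23-3a1 by 0.59 (adjusted p = 1.39e-06). Prnp, the prion protein gene, rose by 0.73 (SE 0.154, adjusted p = 0.0468), above every vehicle array in 4 of 6 arrays. Cyp1a2 had a log2 fold change of 0.21 (adjusted p = 0.197) and Por 0.38 (adjusted p = 0.217).

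In all, 28 probe sets passed at 95.9 mg/kg, 26 up and 2 down. No gene named by 1 symbol was among the decreases, and Plk3, a stress-responsive kinase gene, had -0.27 (adjusted p = 0.17) and Fam234b -0.25 (adjusted p = 0.184). CAR and PXR targets had a median of 0.283 (adjusted p = 1.06e-21 and 4.64e-05 with an estimated correlation). Of the 24, 6 were up over all probe sets and 14 adjusted over the list alone. AhR targets (8 genes) had a median of 0.168 (adjusted p = 0.000194 and 0.00492 with an estimated correlation). Over all probe sets 1 was up, and 3 adjusted over the list alone, Cyp1a1, Ahr (0.77) and Cyp1a2. Ahr had already passed over the list alone at 0.959 (0.61) and 9.59 mg/kg (0.59), where no other member of the list did. Its rise therefore began at lower doses than that of Cyp1a1. The list's call was lost with camera on ranks. Periportal markers fell (median -0.111, 11 of 11 negative, adjusted p = 1.27e-05 and 0.0227 with an estimated correlation), with Gls2 (-0.28) past the threshold over the list alone. Targets of PPARA, the receptor that controls fatty acid oxidation, fell with the preset correlation (28 of 34 negative, median -0.119, estimated-correlation adjusted p = 0.124). Cyp4a3 (-0.33) was down and Cyp4a8 (0.52) was up over the list alone. Stellate cell and fibroblast markers rose (14 of 15 positive, median 0.321, estimated-correlation adjusted p = 0.124). Of its members 7 were up over the list alone, among them Timp1 (0.56), an inhibitor of matrix proteases, and Pdgfra (0.32). Cell cycle genes (median 0.185, estimated 0.271) and NRF2 targets (0.081, estimated 0.398) rose with the preset correlation. Bile acid (-0.052, estimated 0.398), gluconeogenesis (-0.086, estimated 0.16), hepatocyte (-0.03, estimated 0.124) and lymphocyte (-0.119, estimated 0.298) lists fell with it. Leaving out a single array ended 5 of these list calls. The bile acid call was lost without any 1 of 5 arrays (vehicle replicates 1, 3 and 4 and 95.9 mg/kg replicates 1 and 5, adjusted p up to 0.172). The gluconeogenesis call was lost without vehicle replicate 2 or 95.9 mg/kg replicate 1 or 5 (up to 0.0963). The NRF2 call was lost without vehicle replicate 3 (0.0569), the hepatocyte call without vehicle replicate 2 (0.0579) and the lymphocyte call without 95.9 mg/kg replicate 5 (0.0571).

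A fit of these 2 groups alone called 16 probe sets. The Prnp call was lost without any 1 of 7 arrays (adjusted p up to 0.215: vehicle replicates 3, 4, 5 and 6 and 95.9 mg/kg replicates 2, 5 and 6).

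At 959 mg/kg, Cyp1a1 rose 26.3-fold (log2 4.72, SE 0.222, adjusted p = 3.61e-17), to a mean of 9.41 (SD 0.57, n = 6). Its vehicle level of 4.69 lay below the median of all probe sets (5.16), and no detection calls were used, so how far that level stood above background was not measured. Cyp1a2, the constitutive member of the same subfamily, rose by 0.53 (SE 0.0539, adjusted p = 1.06e-07), from 13.16 (SD 0.064, n = 6) to 13.69 (SD 0.045, n = 6). The Cyp2b-subfamily probe set rose 6.06-fold (log2 2.60, SE 0.177, adjusted p = 2.18e-12). Abcc3 rose by 1.17 (SE 0.183, adjusted p = 0.000551) and Ces2c by 0.95 (SE 0.119, adjusted p = 7.81e-06). Each of these lay above every vehicle array in 6 of 6 arrays.

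Other rises at 959 mg/kg were Ugt2b1 (0.90, adjusted p = 1.94e-05), Mmgt1 (0.66, adjusted p = 7.64e-07), Cyp3a23-3a1 (0.64, adjusted p = 1.06e-07), Cndp2 (0.63, adjusted p = 2.18e-06) and Por (0.58, adjusted p = 0.00473). Ahr, which encodes the aryl hydrocarbon receptor, rose by 0.90 (adjusted p = 0.0191), and Slc1a2 by 0.53 (adjusted p = 0.0488), a glutamate transporter gene of pericentral hepatocytes. A probe set assigned to 8 genes of the Ugt1a family rose by 0.26 (adjusted p = 0.0346), and another assigned to the same genes had 0.14 (adjusted p = 0.603). Ak4, a mitochondrial adenylate kinase gene, fell by 0.35 (SE 0.0735, adjusted p = 0.0331). The next decreases did not pass. Pemt, of phosphatidylcholine synthesis, had -0.24 (adjusted p = 0.0557) and Cyp4a3, a fatty acid hydroxylase gene, -0.39 (adjusted p = 0.0795). Acot3, an acyl-CoA thioesterase gene, had -0.42 (adjusted p = 0.111), and Pik3ap1 -0.28 (adjusted p = 0.166). Pemt and Cyp4a3 lay below every vehicle array in 6 of 6 arrays. Nqo1, a quinone reductase gene, had 0.98 (SE 0.218, adjusted p = 0.0575) with 6 of 6 arrays above every vehicle array. Without its highest array, 959 mg/kg replicate 1, Nqo1 had 0.65 (adjusted p = 0.0268). Of the genes followed whatever their values, Cyp4a1, another fatty acid hydroxylase gene, had -0.41 (adjusted p = 0.618) and Thrsp, a thyroid hormone responsive gene, 0.29 (adjusted p = 0.906). Dio1, the deiodinase gene, had 0.085 (adjusted p = 0.931), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, 0.16 (adjusted p = 0.983). The Cyp7a1 value turned negative without vehicle replicate 2 (-0.0167) or 5 (-0.109) or 959 mg/kg replicate 5 (-0.00548).

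In all, 34 probe sets passed at 959 mg/kg, 32 up and 2 down, and 3 of them changed more than 2-fold. A fit of these 2 groups alone called 13 probe sets, and the count was 22 without vehicle replicate 3 and 22 without 959 mg/kg replicate 3. Leaving out a single array ended several calls. These were Ahr (5 arrays: vehicle replicates 3 and 5 and 959 mg/kg replicates 3, 4 and 5, adjusted p up to 0.0921) and Ak4 (7 arrays: vehicle replicates 1 to 4 and 959 mg/kg replicates 2, 3 and 5, up to 0.138). They were also the Ugt1a probe set (7 arrays: vehicle replicates 1, 3, 5 and 6 and 959 mg/kg replicates 1, 5 and 6, up to 0.153) and Slc1a2 (11 arrays: vehicle replicates 2 to 6 and all 6 at 959 mg/kg, up to 0.192). The other probe sets of Ahr (0.10, adjusted p = 0.95), Slc1a2 (-0.048, adjusted p = 0.965) and Ak4 (-0.41, adjusted p = 0.314) did not pass.

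Among the gene lists at 959 mg/kg, the CAR and PXR targets had a median log2 fold change of 0.31 (adjusted p = 1.19e-27 and 7.24e-06 with an estimated correlation). Of the 24, 8 were up over all probe sets and 16 adjusted over the list alone. Cyp3a23-3a1, Cyp2c6v1 (0.42), Ces2c and Ugt2b1 had the smallest p. AhR targets had a median of 0.287 (adjusted p = 9.7e-12 and 4.76e-06 with an estimated correlation). Of the 8, 3 were up over all probe sets, Cyp1a1, Cyp1a2 and Ahr, and 4 adjusted over the list alone, which adds Nqo1. Camera on ranks did not call the list. PPARA targets fell with the preset correlation (25 of 34 negative, median -0.117, adjusted p = 0.124 with an estimated correlation). Cyp4a3 (-0.39) and Ech1 (-0.32) were down and Cyp4a8 (0.51) was up over the list alone, while the beta-oxidation gene Decr1 had -0.16. NRF2 targets rose with the preset correlation (median 0.103, adjusted p = 0.177 with an estimated correlation). Ephx1 (0.39, adjusted p = 0.00504) rose over all probe sets, and Nqo1 and Gsr (0.37), glutathione reductase, over the list alone, with Tkt at 0.14. Ephx1 is also counted among the CAR and PXR targets and Nqo1 among the AhR targets. Of the growth hormone and male-specific genes (15 genes, median -0.031, adjusted p = 0.904), Cyp2c11 rose by 0.24 (adjusted p = 0.0163). That call was lost without any 1 of 5 arrays (vehicle replicates 3 and 5 and 959 mg/kg replicates 3, 4 and 5, adjusted p up to 0.0853). Cyp3a2 (0.13) passed over the list alone, Ghr had -0.13 and Igf1 -0.077.

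Cell cycle genes rose with the preset correlation (30 of 35 positive, median 0.312, adjusted p = 0.271 with an estimated correlation). Tk1 (0.26), Birc5 (0.36) and Kif11 (0.40), genes of DNA synthesis and mitosis, passed over the list alone, and Ccnb1 had 0.65. Heat shock genes rose with the preset correlation (median 0.133, adjusted p = 0.262 with an estimated correlation). Cryab (0.40) was up over the list alone, with Hspa1a at 0.39, Hspb1 0.35 and Hspb8 0.19. Hspa1a had a level of 7.07 in 959 mg/kg replicate 1 (next 5.46), and its log2 fold change without that array was 0.10. The list's call was lost without that array or without vehicle replicate 3 (adjusted p up to 0.0918). Gluconeogenesis genes fell with the preset correlation (median -0.092, adjusted p = 0.177 with an estimated correlation). Asns, asparagine synthetase, had -0.78 and passed over the list alone, and Fbp1 had -0.14, Pc -0.19 and Tat -0.34. The gluconeogenesis call was lost without any 1 of 5 arrays (vehicle replicates 2 and 3 and 959 mg/kg replicates 1, 2 and 6, adjusted p up to 0.186). Fatty acid and triglyceride synthesis genes fell with the preset correlation (median -0.058, adjusted p = 0.0492 and, with an estimated correlation, 0.558). That call was lost without any 1 of 18 arrays (adjusted p up to 0.548). They were vehicle replicates 1, 2, 4, 5 and 6, 0.1 mg/kg replicates 5 and 6, 0.959 mg/kg replicates 1, 2 and 4, and 9.59 mg/kg replicates 1, 2, 4 and 5. The others were replicates 1 and 5 at 95.9 mg/kg and at 959 mg/kg. The desaturase Fads2 (-0.34) was down over the list alone, with Fads1 at -0.14, Elovl5 -0.11 and Srebf1 -0.21. Cholesterol synthesis (median -0.051, adjusted p = 0.5) and bile acid genes (median -0.031, adjusted p = 0.0764) were not called at this dose. Log2 fold changes were -0.16 for Nsdhl, 0.13 for Pmvk, 0.13 for Tm7sf2 (0.045 without 959 mg/kg replicate 2) and 0.15 for Dhcr7. Among bile acid genes they were -0.28 for Abcb4, -0.22 for Nr1h4, -0.36 for Cyp8b1 and -0.41 for Abcg8. Thyroid hormone genes were not called at any dose (at 959 mg/kg median 0.004, adjusted p = 0.723). Serpina7, which encodes thyroxine-binding globulin, had -0.82 (SE 0.311), Gpd2 -0.34 and Slc16a10 0.17.

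The lists of p53 and DNA damage, unfolded protein and integrated stress, acute phase and circadian clock genes were not called at any dose. At 959 mg/kg, p53 and DNA damage genes had a median of -0.001 (adjusted p = 0.648), with Perp at 0.15, Polk at 0.13, Mdm2 at 0.13 and Cdkn1a at 0.23 (0.0321 without 959 mg/kg replicate 4). Unfolded protein and integrated stress genes had a median of -0.008 (adjusted p = 0.589), with Chac1 at -0.92, Manf at 0.16 and Herpud1 at -0.18. Acute phase genes had a median of -0.022 (adjusted p = 0.723), with Crp at 0.22, Itih4 at -0.11, Fgb at -0.096 and Cxcl1 at 0.80. Circadian clock genes had a median of 0.016 (adjusted p = 0.904), with Hlf at 0.21, Nfil3 at -0.21, Wee1 at 0.14 and Bmal1 at -0.11 (-0.0643 without 959 mg/kg replicate 5). Of these, Crp, C-reactive protein, passed over its list alone at 95.9 and 959 mg/kg and Mdm2 at 95.9 mg/kg (0.26).

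Among markers of cell types and lobule zones at 959 mg/kg, pericentral markers rose with the preset correlation (10 genes, median 0.086, adjusted p = 0.108 with an estimated correlation). Cyp1a2 and Slc1a2 passed over all probe sets, Oat had 0.30 and Axin2 0.13. Periportal markers fell with the preset correlation (median -0.118, adjusted p = 0.232 with an estimated correlation), with Gls2 at -0.21, Cdh1 at -0.18, Hal at -0.21 and Hsd17b13 at -0.13. That call was lost without 959 mg/kg replicate 2, 5 or 6 (adjusted p up to 0.0924). Cholangiocyte markers rose with the preset correlation (9 of 9 positive, median 0.108, adjusted p = 0.129 with an estimated correlation), with Krt7 at 0.33, Krt19 at 0.59, Epcam at 0.28 and Spp1 at 0.23. Their call was lost without 959 mg/kg replicate 5 (adjusted p = 0.0932). The remaining lists were not called at 959 mg/kg. Hepatocyte markers had a median of -0.014 (adjusted p = 0.234), with Apoa2 at 0.097 and Hnf4a at -0.17. Stellate cell markers had 0.095 (adjusted p = 0.24), with Timp1 at 0.40 (up over the list alone), Rgs5 at 0.31, Lum at 0.75 (0.313 without 959 mg/kg replicate 5) and Pdgfra at 0.14 (0.234 without vehicle replicate 1). For endothelial markers it was -0.055 (adjusted p = 0.24), with Kdr at -0.12, Tek at -0.096, Flt1 at 0.091 and Stab2 at -0.10. Macrophage markers had -0.16 (adjusted p = 0.293), with Cd14 at 0.31, Csf1r at -0.21, Lyz2 at 0.24 (0.474 without 959 mg/kg replicate 2) and Adgre1 at -0.26. For lymphocyte markers it was -0.114 (adjusted p = 0.265), with Cd79b at 0.15, Gzmb at -0.25, Cd3e at -0.18 (-0.0616 without 959 mg/kg replicate 6) and Cd2 at -0.11. The interferon response had -0.089 (adjusted p = 0.377), with Ifit2 at -0.25, Cxcl10 at 0.38 (0.0619 without 959 mg/kg replicate 1), Ifih1 at -0.11 and Oasl at -0.16.

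Neutrophil, erythroid and exocrine pancreas markers were not called at any dose. At 959 mg/kg the neutrophil markers had a median of 0.024 (adjusted p = 0.835), with Mmp8 at 0.11, Np4 at 0.11, Cxcr2 at -0.072 and Camp at -0.075. Erythroid markers had -0.067 (adjusted p = 0.212), with Ahsp at -0.27, Slc4a1 at -0.14, Hbb at -0.093 and Alas2 at -0.067 (0.005 without vehicle replicate 4). Exocrine pancreas markers had 0.029 (adjusted p = 0.691), with Cpa1 at 0.12, Cela1 at 0.15 (0.0442 without vehicle replicate 6), Prss2 at 0.093 and Clps at -0.080.

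**Figure D2:**
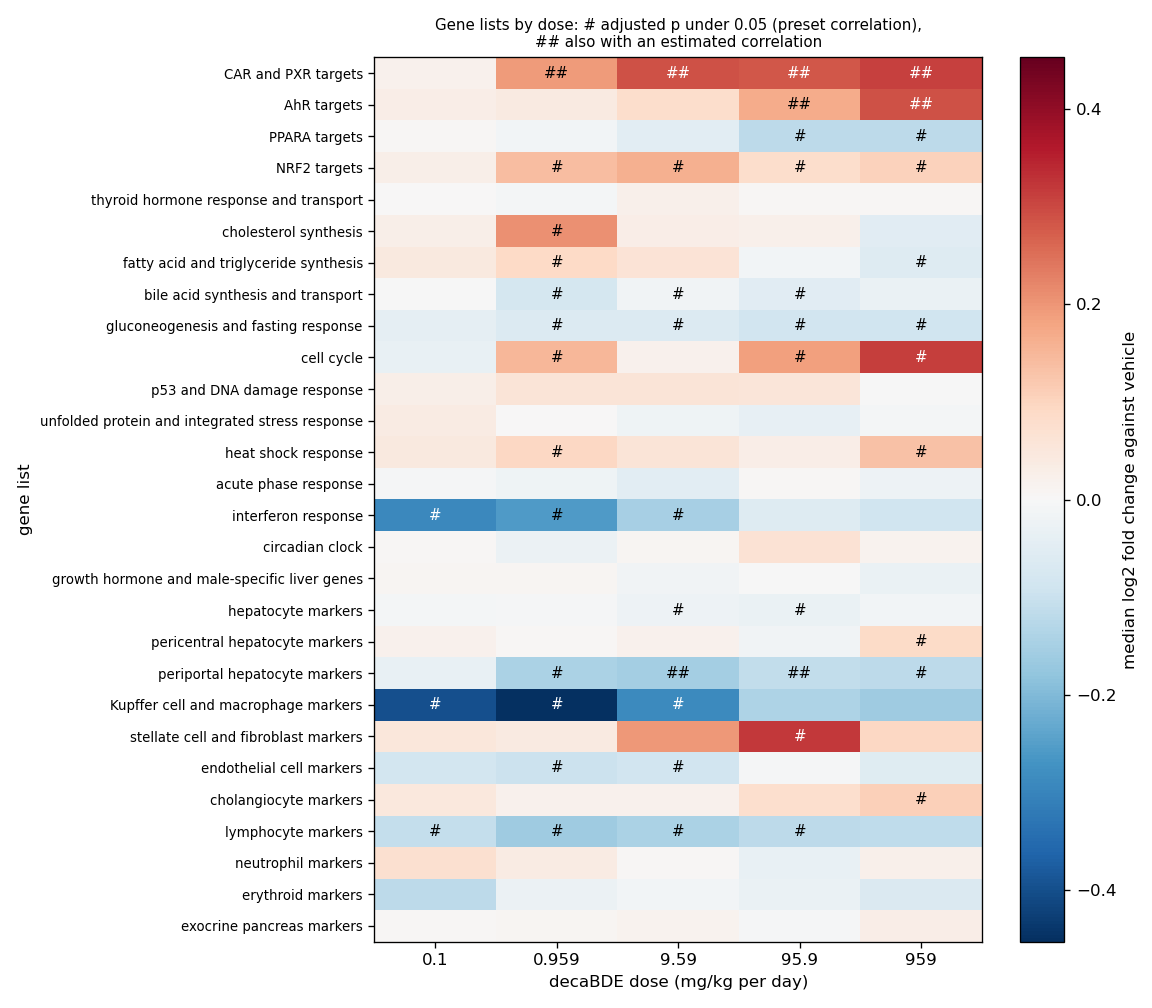
Median log2 fold change against vehicle (colour) of 28 gene lists (vertical axis) at 5 decaBDE doses in mg/kg (horizontal axis), with 1 mark for lists called by camera with a preset correlation and a doubled mark for lists also called with an estimated correlation. The CAR and PXR targets carry the doubled mark from 0.959 mg/kg (median 0.193) to 959 mg/kg (median 0.31), the AhR targets at 95.9 and 959 mg/kg, and the periportal markers at 9.59 and 95.9 mg/kg.

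Over all doses, 48 of 140 list tests were called with the preset correlation, 20 up and 28 down, and 8 with an estimated correlation: CAR and PXR targets at 4 doses, AhR targets at 2 and periportal markers at 2. In 22 of 140 tests the direction of the test, the median and the mean differed in sign, 0 of them called. With the preset correlation, the calls of 20 of the 48 were lost when 1 array was left out, and none of the 8 was among them. The tests with an estimated correlation were not repeated without an array.

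The comparison of 959 with 95.9 mg/kg asked whether the top doses differed, and Cyp1a genes did. Cyp1a1 was higher at 959 mg/kg by a log2 of 3.09 (SE 0.222, 95% interval 2.64 to 3.54, adjusted p = 2.25e-11), and Cyp1a2 by 0.32 (0.214 to 0.432, adjusted p = 0.0121). The other probe sets did not pass; Nbea had -0.36 (adjusted p = 0.355) and F8, coagulation factor VIII, -0.29 (adjusted p = 0.977). Genes of the CAR and PXR type did not differ detectably. The difference was 0.048 (-0.311 to 0.407) for the Cyp2b-subfamily probe set, 0.045 (-0.0867 to 0.178) for Cyp3a23-3a1. It was -0.020 (-0.259 to 0.219) for Ugt2b1, -0.0087 (-0.251 to 0.233) for Ces2c and 0.086 (-0.285 to 0.456) for Abcc3. Por had 0.20 (-0.00911 to 0.411, adjusted p = 0.977). limma called 2 probe sets, with 1483 (4.78%) at an unadjusted p under 0.05. The Cyp1a2 call was lost without any 1 of 5 arrays (adjusted p up to 0.0868: 95.9 mg/kg replicates 1, 2 and 5 and 959 mg/kg replicates 1 and 2), which left a count of 1, and a fit of these 2 groups alone also called 1.

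Other pairs of doses were compared after the values against vehicle had been seen. From 9.59 to 95.9 mg/kg, Cyp1a1 was the 1 probe set called. From 9.59 to 959 mg/kg, Cyp1a1 and Cyp1a2 were the 2 called. From 0.959 to 9.59 mg/kg, the 1 called had no gene symbol and differed from vehicle at neither dose (adjusted p = 0.756 and 0.397). Genes of the CAR and PXR type did not pass at this step, yet several unadjusted 95% intervals were positive throughout. They were 0.219 to 0.703 for Ces2c, 0.129 to 0.606 for Ugt2b1, 0.133 to 0.874 for Abcc3 and 0.121 to 0.838 for the Cyp2b-subfamily probe set. For Cyp2c6v1 (-0.0534 to 0.134) and Por (-0.146 to 0.274) the interval held both signs.

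The test for any difference among doses and the test for a straight line in dose rank used all 6 groups. The fitted line for Cyp1a1 had a slope of 0.81 in log2 per dose step (SE 0.0374, adjusted p = 2.39e-17). Its rise was not even over the steps. Cyp1a1 differed by 0.0133 from 0.959 to 9.59 mg/kg, by 1.63 from 9.59 to 95.9 mg/kg and by 3.09 from 95.9 to 959 mg/kg. Slopes were 0.31 for Cyp3a9, a P450 gene (SE 0.0537, adjusted p = 0.00118), and 0.24 for Abcc3 (SE 0.0309, adjusted p = 1.01e-05). They were 0.23 for Ces2c (SE 0.0201, adjusted p = 2.26e-09) and 0.21 for Ugt2b1 (SE 0.0199, adjusted p = 1.06e-08). Among the 11 genes that fell were the acyl-CoA thioesterase gene Acot3, with a slope of -0.095 (adjusted p = 0.00244), and 4 others. Slopes were -0.087 for Cyp4a3 (adjusted p = 0.00156), -0.096 for Acot4 (adjusted p = 0.0344), -0.078 for Fads2 (adjusted p = 0.016) and -0.10 for Aldh18a1, of proline synthesis (adjusted p = 0.0198). In all, 122 probe sets had a trend, 104 up and 18 down, and 42 differed at any dose.

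A line in dose in mg/kg called 9 probe sets, and of these 10 genes only Cyp1a1 and Ces2c passed it. Without the 959 mg/kg group the 5 falling genes did not pass, while their slopes stayed near those above. They were -0.0927 for Acot3 (adjusted p = 0.0766), -0.0859 for Cyp4a3 (0.0802), -0.0863 for Acot4 (0.26), -0.072 for Fads2 (0.19) and -0.0946 for Aldh18a1 (0.175). The Acot4 call was also lost without any 1 of 13 arrays (up to 0.105: vehicle replicates 1, 2 and 4, 0.1 mg/kg replicates 2, 3 and 5, 95.9 mg/kg replicates 1, 2 and 4 and 959 mg/kg replicates 1, 4, 5 and 6), and the Aldh18a1 call without any 1 of 5 (up to 0.0652: vehicle replicates 2, 3 and 4 and 959 mg/kg replicates 3 and 4).

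Calls were shared between doses in 1 direction. Of the calls at 0.959 and 9.59 mg/kg, 7 were shared, and 18 were shared between 9.59 and 95.9, 19 between 9.59 and 959 and 19 between 95.9 and 959 mg/kg. All shared calls were rises, against 0.0096, 0.028, 0.034 and 0.027 expected for independent lists. The doses share vehicle arrays, which alone correlated simulated fold changes at 0.5, 0.502, 0.5 and 0.499 across probe sets without shared calls (mean 0). As this simulation held no dose effect, it does not show how far the shared vehicle adds to the overlap of real calls. The measured correlations were 0.523, 0.547, 0.537 and 0.594, and 0.0731, 0.104, 0.112 and 0.145 when each dose was compared with its own share of the vehicle arrays, 3 for each.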

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

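All tests of explanations in this part were chosen after the result was seen. The highest and the lowest array of each group of 6 was compared with its nearest neighbour, for each gene named in the text and each list score, and an array is given here where that gap, as a ratio to the range of its group, exceeded Dixon's 95% critical value. This held for 70 of 1098 groups (6.38%), where chance gives about 1 in 20. The counts lean on 1 array: 10 of the 70 came from replicate 6 of the 0.1 mg/kg group, the array with the lowest weight (0.517). No array was left out for this; without that array 0 probe sets were called at 0.1 mg/kg and 63, against 42, for any dose.

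The interferon and macrophage genes differed widely between arrays of 1 group. The median SD within groups was 0.447 for interferon genes and 0.404 for macrophage markers, against 0.137 over all 14217 genes; among vehicle arrays Irf7, the interferon regulator, ran from 6.21 to 8.90, Mx2, an antiviral gene, from 4.74 to 7.57 and Clec4f, a Kupffer cell receptor, from 9.70 to 11.04. The macrophage and interferon scores, as deviations from group means, rose together (Pearson's r 0.92, rho 0.885, each permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 4e-05 over 8 relations, r 0.898 without the 2 farthest arrays). Dose is argued against as the source of the whole spread, since the SD of the interferon score among vehicle arrays was 1.08 times that over all arrays. For the macrophage score these SDs were 0.307 and 0.332. This restates the spread within vehicle and does not test for an added effect of dose. Between groups lay 10% of the variance of the interferon score (permutation p = 0.64) and 19.1% of that of the macrophage score (permutation p = 0.25). A lower share of hepatocytes would raise all other cells' scores alike. Per unit of the macrophage score, the endothelial slope was 0.091 (95% interval 0.007 to 0.175) and the stellate slope -0.138 (-0.421 to 0.145). For cholangiocytes it was -0.031 (-0.179 to 0.116). These 3 scores thus rose far less than the macrophage score. The lymphocyte score did rise with the macrophage score (r 0.785, rho 0.814, each adjusted p = 4e-05, r 0.729 without the 2 farthest), with a slope of 0.296 (95% interval 0.207 to 0.384). Since a score that moved closely with the macrophage score also had a slope far below 1, the low slopes cannot decide on the share of hepatocytes. RNA quality cannot be told apart from a difference between rats, because the interferon score went with the 3' to 5' difference of actin (r -0.468, permutation p = 0.0098, adjusted p = 0.02; rho -0.477, p = 0.008, adjusted p = 0.016; r -0.347 without the 2 farthest), while for GAPDH the relation did not pass (r -0.017, p = 0.93, adjusted p = 0.93; rho -0.127, p = 0.51, adjusted p = 0.51; r -0.138 without the 2 farthest); a difference in immune state between rats stays open and untested, since the labels give no measure of it.

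Mmgt1 was highest in vehicle replicate 1 (10.03, next 9.75, ratio 0.687). Pdgfra was highest in vehicle replicate 1 (8.06, next 7.58, ratio 0.646). B3gnt5 was lowest in vehicle replicate 2 (3.05, next 3.34, ratio 0.675). Irf7 was lowest in vehicle replicate 2 (6.21, next 7.89, ratio 0.626). Clec4f was lowest in vehicle replicate 2 (9.7, next 10.64, ratio 0.7). The Kupffer cell and macrophage markers score was lowest in vehicle replicate 2 (-0.41, next 0.23, ratio 0.791). Np4 was lowest in vehicle replicate 4 (3.26, next 3.42, ratio 0.732). Hspa1a was lowest in vehicle replicate 5 (4.9, next 5.19, ratio 0.637). The pericentral hepatocyte markers score was lowest in vehicle replicate 5 (-0.25, next -0.03, ratio 0.754). Asns was lowest in vehicle replicate 6 (7.46, next 8.08, ratio 0.683). Cela1 was lowest in vehicle replicate 6 (9.53, next 10.04, ratio 0.644).

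Acot3 was lowest in 0.1 mg/kg replicate 1 (6.02, next 6.42, ratio 0.693). Prnp was highest in 0.1 mg/kg replicate 1 (7.33, next 6.88, ratio 0.758). Pmvk was lowest in 0.1 mg/kg replicate 1 (9.46, next 9.65, ratio 0.653). Bmal1 was highest in 0.1 mg/kg replicate 2 (7.63, next 7.44, ratio 0.657). The periportal hepatocyte markers score was lowest in 0.1 mg/kg replicate 2 (-0.11, next 0.04, ratio 0.636). Adamts8 was highest in 0.1 mg/kg replicate 4 (3.2, next 3.06, ratio 0.696). Nsdhl was lowest in 0.1 mg/kg replicate 6 (11.34, next 11.55, ratio 0.734). Srebf1 was lowest in 0.1 mg/kg replicate 6 (9.5, next 9.86, ratio 0.757). Fbp1 was lowest in 0.1 mg/kg replicate 6 (12.63, next 12.8, ratio 0.7). Birc5 was highest in 0.1 mg/kg replicate 6 (5.92, next 5.66, ratio 0.756). Manf was highest in 0.1 mg/kg replicate 6 (11.79, next 11.33, ratio 0.668). Cd79b was highest in 0.1 mg/kg replicate 6 (5.58, next 5.29, ratio 0.688). Hbb was highest in 0.1 mg/kg replicate 6 (13.1, next 12.54, ratio 0.632). Alas2 was highest in 0.1 mg/kg replicate 6 (7.7, next 7.12, ratio 0.737). Sesn2 was lowest in 0.1 mg/kg replicate 6 (6.49, next 7.01, ratio 0.646). Wapl was lowest in 0.1 mg/kg replicate 6 (5.51, next 5.78, ratio 0.641).

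The Ugt1a probe set was lowest in 0.959 mg/kg replicate 1 (12.2, next 12.29, ratio 0.715). Sesn2 was lowest in 0.959 mg/kg replicate 1 (6.84, next 7.1, ratio 0.655). Mmp8 was lowest in 0.959 mg/kg replicate 3 (3.3, next 3.46, ratio 0.886). Hnf4a was highest in 0.959 mg/kg replicate 4 (12.23, next 11.84, ratio 0.72). Mx2 was lowest in 0.959 mg/kg replicate 4 (3.89, next 5.63, ratio 0.659). Slc16a10 was lowest in 0.959 mg/kg replicate 5 (5.91, next 6.11, ratio 0.669). Cxcl10 was highest in 0.959 mg/kg replicate 5 (5.67, next 5.4, ratio 0.821). The circadian clock score was lowest in 0.959 mg/kg replicate 5 (-0.13, next -0.03, ratio 0.632). Hspb8 was lowest in 0.959 mg/kg replicate 6 (9.78, next 9.86, ratio 0.643).

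Ifit2 was highest in 9.59 mg/kg replicate 2 (8.75, next 8.47, ratio 0.659). Cxcr2 was lowest in 9.59 mg/kg replicate 4 (3.35, next 3.52, ratio 0.66). Aldh18a1 was highest in 9.59 mg/kg replicate 5 (6.55, next 6.1, ratio 0.637). Tat was highest in 9.59 mg/kg replicate 5 (10.27, next 9.66, ratio 0.707). Hlf was lowest in 9.59 mg/kg replicate 5 (7.4, next 7.79, ratio 0.685). The AhR targets score was lowest in 9.59 mg/kg replicate 5 (-0.26, next -0.13, ratio 0.643).

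Cyp7a1 was lowest in 95.9 mg/kg replicate 1 (9.81, next 10.52, ratio 0.647). Cpa1 was highest in 95.9 mg/kg replicate 2 (4.66, next 4.54, ratio 0.733). Prss2 was lowest in 95.9 mg/kg replicate 2 (2.7, next 2.94, ratio 0.631). Abcc3 was highest in 95.9 mg/kg replicate 3 (6.74, next 6.32, ratio 0.648). Np4 was highest in 95.9 mg/kg replicate 3 (3.79, next 3.49, ratio 0.658). Clps was highest in 95.9 mg/kg replicate 3 (4.09, next 3.58, ratio 0.697). Cyp3a2 was highest in 95.9 mg/kg replicate 4 (14.29, next 14.19, ratio 0.76). The acute phase response score was highest in 95.9 mg/kg replicate 4 (0.22, next 0.02, ratio 0.651). Cyp8b1 was lowest in 95.9 mg/kg replicate 5 (10.58, next 10.96, ratio 0.69). Hsd17b13 was highest in 95.9 mg/kg replicate 5 (11.31, next 11.18, ratio 0.657). Nfil3 was highest in 95.9 mg/kg replicate 6 (9.15, next 8.58, ratio 0.819). Krt19 was highest in 95.9 mg/kg replicate 6 (6.37, next 5.83, ratio 0.697).

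Nqo1 was highest in 959 mg/kg replicate 1 (9.98, next 8.22, ratio 0.807). Chac1 was highest in 959 mg/kg replicate 1 (7.73, next 6.46, ratio 0.766). Hspa1a was highest in 959 mg/kg replicate 1 (7.07, next 5.46, ratio 0.785). Ugt2b1 was lowest in 959 mg/kg replicate 2 (12.83, next 13.31, ratio 0.767). Ak4 was lowest in 959 mg/kg replicate 2 (9.52, next 9.85, ratio 0.663). Tm7sf2 was highest in 959 mg/kg replicate 2 (11.68, next 11.27, ratio 0.626). Lyz2 was lowest in 959 mg/kg replicate 2 (9.48, next 10.68, ratio 0.708). Cdkn1a was highest in 959 mg/kg replicate 4 (9, next 7.87, ratio 0.859). The periportal hepatocyte markers score was highest in 959 mg/kg replicate 4 (0.29, next 0.01, ratio 0.703). Bmal1 was lowest in 959 mg/kg replicate 5 (7.12, next 7.39, ratio 0.696). Col1a2 was highest in 959 mg/kg replicate 5 (9.42, next 8.15, ratio 0.822). Wapl was lowest in 959 mg/kg replicate 5 (5.7, next 5.82, ratio 0.631). The fatty acid and triglyceride synthesis score was lowest in 959 mg/kg replicate 5 (-0.35, next -0.09, ratio 0.638). The endothelial cell markers score was highest in 959 mg/kg replicate 5 (0.13, next -0.01, ratio 0.839). Cd3e was lowest in 959 mg/kg replicate 6 (4.29, next 4.92, ratio 0.865). The exocrine pancreas markers score was highest in 959 mg/kg replicate 6 (0.11, next 0.02, ratio 0.706).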

How the results depend on the processing

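Apart from those named below as chosen after seeing the data, the alternatives were planned. The count at 0.1 mg/kg stayed at 0 under every alternative run. A fit of only the arrays of the 2 groups compared, with fewer arrays to estimate the spread, called 1 probe set at 0.959 mg/kg, 19 at 9.59, 16 at 95.9 and 13 at 959 mg/kg, and 1 for 959 against 95.9 mg/kg, against 9, 36, 28, 34 and 2. Only the brightest probe set of each gene, with fewer probe sets tested, gave 5 at 0.959 mg/kg. Leaving out 1 array gave 4 to 10 calls at 0.959 mg/kg, 20 to 45 at 9.59, 19 to 38 at 95.9, 22 to 42 at 959 mg/kg, 31 to 63 for any dose, 92 to 156 for the trend, 1 to 2 for 959 against 95.9 mg/kg and 41 to 50 for the lists; the cause was not tested beyond the lower number of arrays. Without 0.1 mg/kg replicate 6, a choice made after seeing the data for the comparisons that do not hold it, 10, 40, 31 and 42 probe sets passed at the 4 higher doses; for any dose, where leaving it out was planned, the count rose from 42 to 63, the most of any array left out. The trend count fell from 122 to 9 with a line in dose in mg/kg, a scale on which the lower doses lie close to vehicle; it was 113 with log10 dose and 91 without the highest dose. Of the 48 list calls, 8 held with an estimated correlation and 12 with fry; the cause was not tested. The remaining counts stayed within 1.5 times.

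With the replicate block, the counts were 0, 6, 28, 26 and 29 at the 5 doses, 37 for any dose, 104 for the trend, 2 for 959 against 95.9 mg/kg and 48 for the lists; nothing in the labels pairs the numbers, and the residuals of arrays with the same number had a mean correlation of -0.022 against 0.0045 for other numbers. The interferon score as a covariate, chosen after seeing the data, gave 0, 10, 43, 33 and 40 at the 5 doses, 41, 117 and 2, and 43 lists. The interferon list cannot be judged with its own score as covariate, and of the other 45 list calls 2 were lost. Among named genes, 51 calls were tested again: 13 were lost when 1 array was left out, 15 of 41 in a fit of the compared groups alone, 5 without variance moderation, 5 with the replicate block, 3 after subtracting array medians, 2 with an intensity trend and 1 each with renewed quantile normalization and array weights. Of the 104 genes named at 959 mg/kg that did not pass, 46 had a log2 fold change that moved by over 1.5 times or changed sign when 1 array was left out, as 0 of the 17 that passed had. This count was chosen after seeing the data. A gene passes only with a fold change large against its standard error, so the contrast largely follows from the threshold and does not test the calls. Slc1a2 at 959 mg/kg was the 1 call that reversed: its other probe set, at a mean level of 2.96, had -0.0481 against 0.53, and the cause was not tested. No detection calls were used, so how far that probe set, Adamts8 and, in vehicle, Cyp1a1, all below the median level of 5.16, stood above background was not measured.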

Other observations

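The genes in the next 3 paragraphs were chosen after their values were seen, as were the tests of explanations further below; the counts over other groupings of the arrays were planned.

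App, the amyloid precursor protein gene, and Vav2, a guanine nucleotide exchange factor gene, were called through several probe sets each. App rose by 0.52 at 9.59 mg/kg (brightest probe set, adjusted p = 0.00466), 0.60 at 95.9 mg/kg (adjusted p = 0.00047) and 0.43 at 959 mg/kg (adjusted p = 0.0434). Its other probe sets rose by 0.53 (adjusted p = 0.00382) and 0.52 (adjusted p = 0.0124) at 959 mg/kg. Vav2 rose by 0.51 at 9.59 mg/kg (brightest probe set, adjusted p = 0.000267), 0.48 at 95.9 mg/kg (adjusted p = 0.000932) and 0.38 at 959 mg/kg (adjusted p = 0.0207). Of the enzymes of aldehyde and glutathione metabolism, Aldh1a1 rose by 0.47 at 9.59 mg/kg (adjusted p = 0.0116) and Gstm1 by 0.28 at 959 mg/kg (adjusted p = 0.0434).

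Falls outside the brightest probe sets were those of Cars1, a cysteinyl-tRNA synthetase gene, by 0.41 at 959 mg/kg (adjusted p = 0.00923), and Wapl, a cohesin regulator gene, by 0.39 at 9.59 mg/kg (adjusted p = 0.0116). The brightest probe sets had -0.36 for Cars1 (adjusted p = 0.255) and -0.033 for Wapl (adjusted p = 0.949).

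Some list members passed over their list alone and not over all probe sets. At 95.9 mg/kg they included the stellate cell and smooth muscle genes Tagln (0.80, adjusted p = 0.451) and Col1a2 (0.69, adjusted p = 0.474), the proliferation marker Mki67 (0.66, adjusted p = 0.277) and the p53 target Sesn2 (-0.43, adjusted p = 0.285), which also passed over its list alone at 0.1 mg/kg (-0.40, adjusted p = 1). At 9.59 mg/kg they included Abcg5, the partner of Abcg8 (-0.95, adjusted p = 0.236), Cps1, the entry enzyme of the urea cycle (-0.17, adjusted p = 0.318), and Sds, serine dehydratase (-0.36, adjusted p = 0.354). At 0.959 mg/kg they included Mrc1, the mannose receptor of macrophages and sinusoidal endothelium (-0.35, adjusted p = 0.497).

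Other groupings of the same arrays into groups of the same sizes were counted, 100 per comparison with the real one. At 0.959 mg/kg, 1 of 100 gave as many calls, the real grouping itself (9 against a highest other of 6). The margin was narrow, since the real count fell below 6 without some single arrays, so this count alone does not firmly exclude chance. With 1 of 100 each, chance could be excluded at 9.59 mg/kg (36 against 4), 95.9 mg/kg (28 against 6) and 959 mg/kg (34 against 1). The same held for any dose (42 against 3) and the trend (122 against 1). For 959 against 95.9 mg/kg, 2 of 100 gave at least the real 2 calls, the real grouping included. The highest other gave 4, so a count this small does not exclude chance. At 0.1 mg/kg the count says nothing on chance, since the real grouping gave 0 calls and all 100 of 100 must give as many; the highest other gave 7. For the lists, 1 of 100 gave as many as the real 48, the real grouping itself, and the highest other gave 45. The number of lists called with the preset correlation thus exceeds what the spread between arrays gives by little. It could also fall below 45 when 1 array was left out. For lists called only with the preset correlation, the count therefore does not exclude chance.

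For genes of the CAR and PXR type, no further rise was detected from 9.59 to 959 mg/kg. Intervals for this difference were wide, at -0.312 to 0.405 for the Cyp2b-subfamily probe set and -0.478 to 0.263 for Abcc3. Members moved both ways: against vehicle, Cyp3a9 had 0.88 at 9.59 and 1.39 at 959 mg/kg, and Aldh1a1 had 0.47 and 0.33. A signal ceiling of the arrays is argued against only for dimmer probe sets. Apart from Cyp1a1, an AhR target, 16 probe sets called up at 95.9 mg/kg had a mean level below 10, far from the highest values of the arrays. They differed by -0.007 between 959 and 9.59 mg/kg (95% interval -0.112 to 0.098) after a rise of 0.525 from vehicle to 9.59 mg/kg. These 16 were chosen by level and call, not by membership of the CAR and PXR list. The 9 brighter ones, the Cyp2b-subfamily probe set among them, differed by 0.018. A ceiling would also leave bright probe sets flat, so for these 9 the test cannot decide. That the absorbed dose of every component stopped rising is argued against by the 2 probe sets, Cyp1a1 and Cyp1a2, that differed between these doses. A full response of the receptors at 9.59 mg/kg, and a limit to the absorption of decaBDE itself with a minor component still rising, stay open and untested.

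The rise of Cyp1a1 and Cyp1a2 at 959 mg/kg was set against 2 explanations. A larger share of pericentral hepatocytes is argued against, since the other 9 pericentral markers had a median log2 fold change of 0.045 (SD 0.192) against 0.53 for Cyp1a2, although 1 of them, Slc1a2, moved as far. A few arrays did not carry it: 6 of 6 arrays lay above every vehicle array for Cyp1a1. Activation of the aryl hydrocarbon receptor by decaBDE, and by a trace component of the preparation that reached an active level at the highest doses, stay open, since the labels give no composition and the groups differ in both together.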
